A study of Mus musculus with 12 samples.

How the data were processed

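RNA was extracted from mouse lung with a Qiagen RNEasy kit and libraries were made with an Illumina TruSeq mRNA kit, per the labels' protocols, and the strain label is Balb/cJ. The authors processed the reads with cutadapt 1.18, STAR 2.7.6a and RSEM 1.3.0, per the submitters' processing notes, which name the builds GRCm38 and GRCh38 without saying what each was used for. The deposited table holds a signal per gene and library, CPM (read counts scaled to library size) adjusted by the trimmed mean of M-values (TMM), as the authors named the table, on a linear scale. In every library all values were whole multiples of the value of 1 read (100% at a tolerance of 0.01), so read counts could be recovered by division. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain, as are near-identical copies such as Hspa1a and Hspa1b, Chil3 and Chil4, or Sprr2a2 and Sprr2a3.

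The table held 49585 genes. Of their identifiers 49326 (99.5%) matched GENCODE M21 on GRCm38 without the version and 43749 with it, and coordinates are from that annotation. Symbols that had turned into dates (26) were replaced from M21 where the identifier matched, and 190 entries shared a symbol with another. Recovered totals ran from 20708884 to 30229446 reads per library. A count of 0 then allows a level of up to 3 reads, and this covers counting error only. Replicate pairs had Pearson correlations of 0.970 to 0.993 on the log2 scale and differed by at least 11.3 times counting noise (chi-square per degree of freedom), so no library was a copy of another.

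Genes at 1 CPM or more in at least 3 of the 12 libraries were tested, 16126 in all. Values were log2(CPM + 0.5), which understates the change of low genes. The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, in 1 fit over the 4 groups of 3 libraries with 8 residual degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05. Comparisons were Af against PBS in each genotype, KO against WT under each exposure and averaged over both, and the interaction. The library numbers come from the labels, are unique to each library, and run from 9 to 14 for KO and from 15 to 20 for WT, so that genotype and library number coincide. Within each genotype every PBS number lies below every Af number, so exposure follows library number there as well. P-values measure the spread between these libraries.

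Gene lists (41, of which 39 had at least 5 tested members) were fixed before the data were examined, as were the tests, alternatives and the rule for named genes. List tests used camera with a preset correlation of 0.01 and with an estimated correlation, and fry. Per comparison the rule took the 10 highest and 10 lowest changes past the threshold with groups that did not overlap (chance gives 10% of genes for 3 against 3; no such condition for the averaged comparison and the interaction), up to 4 members with the smallest p from each list, Rgs4 and Rgs5, and any interaction gene, leaving out immunoglobulin and T cell receptor segments, Gm and Rik names. Genes named outside it were chosen after their values were seen: Fkbp5 under Af, Cirbp, Rbm3, Gm7068, Krt13, Krt6b, Sprr3, Dsg3 and the genes near Rgs4. So were Krt4, Krt5, Krt6a, Krt14, Krt78 and Dsc3. Lists of heat shock factor 1 targets, cold-inducible genes, glucocorticoid receptor targets and squamous epithelium genes were also made after the data were seen.

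Alternatives were other pseudocounts, filters, rescaling, variance models, array weights, fits of the compared groups alone and leaving out each library. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered counts, where an adjusted p that DESeq2 left empty stayed empty, and a fit without WT_PBS 17 and KO_Af 12. The test was tested on simulated data with 100 genes changed at each size among 16126. All groups were given the WT_PBS means, changes were placed in KO_PBS alone, and genes were drawn independently. For KO against WT under PBS the test recovered 66% of 2-fold and 25% of 1.5-fold changes with 7 wrong calls. In a simulated Af comparison in WT without change it made 0 calls. Figures were drawn with matplotlib 3.10.9.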

Results

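Poly-A RNA was sequenced from lungs of wild-type (WT) mice and of mice lacking Rgs4 (KO), a regulator of G protein signalling that shortens signals from Gq- and Gi-coupled receptors. Mice of each genotype were exposed to the mould Aspergillus fumigatus (Af) or to phosphate-buffered saline (PBS) as control, in a study of the role of Rgs4 in asthma, and the form, route and dose of Af are not given in the sources used here. The 4 groups held 3 libraries each, 12 in all, named here by group and library number: WT_PBS 15 to 17, WT_Af 18 to 20, KO_PBS 9 to 11 and KO_Af 12 to 14. Total counts ran from 20708884 to 30229446 per library. The first principal component held 68.4% of the variance and separated all Af from all PBS libraries. KO_Af 12 stood apart on the second, which held 8.41%. All levels below are CPM as deposited (read counts scaled to library size), given as mean ± SD with n = 3 libraries per group, and fold changes are on the log2(CPM + 0.5) scale with adjusted p-values from limma.

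Rgs4 (ENSMUSG00000026678, chromosome 1, 169741477 to 169747642, minus strand, GRCm38) was measured first, since the design rests on its loss. Its level was 22.9 ± 2.63 CPM in WT_PBS and 0.892 ± 0.282 CPM in KO_PBS, which left 3.89% of the WT level. Under Af it was 45.1 ± 3.27 CPM in WT and 1.15 ± 0.311 CPM in KO, or 2.56% of WT. Every KO library lay below every WT library, with 13 to 32 Rgs4 reads per KO library against 472 to 1304 per WT library. The difference between genotypes was significant under PBS (limma adjusted p = 7.97e-07) and under Af (adjusted p = 1.27e-07). In WT lungs Af raised Rgs4 1.95-fold (log2 0.96 ± 0.18 SE, adjusted p = 9.42e-04). Rgs5, the neighbouring family member, was not called between genotypes over both exposures (log2 0.44, limma adjusted p = 0.336).

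**Figure D1:**
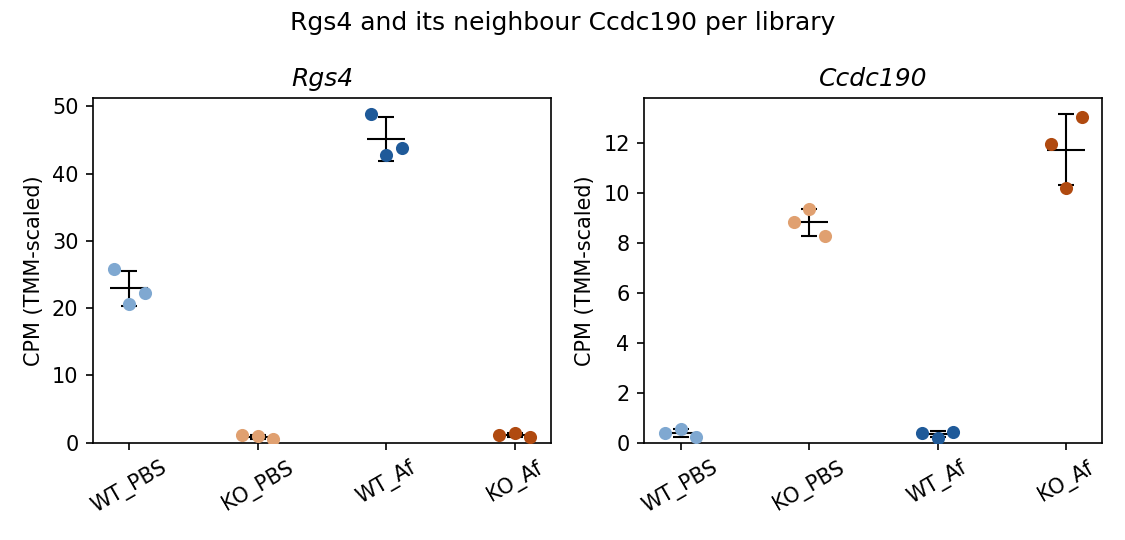
CPM of Rgs4 (left) and of the neighbouring gene Ccdc190 (right) in each library, with points for libraries, a horizontal line for the group mean and bars for the SD (n = 3). Rgs4 lies near 1 CPM in all KO libraries and Ccdc190 under 1 CPM in all WT libraries.

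The response of WT lungs to Af was compared first. Type 2 effector genes were among the genes with the highest rises: Retnla, a secreted product of alternatively activated macrophages and airway cells, went from 76.1 ± 15 to 8178 ± 987 CPM (log2 6.75 ± 0.22 SE). Arg1, which turns arginine into ornithine, rose 134-fold, and the chemokine genes Ccl8 and Ccl7 rose 82.6-fold and 40.8-fold. The goblet cell genes Clca1, Muc5ac (the main inducible airway mucin) and Itln1 rose by log2 6.37, 3.68 and 4.76. Among club cell genes, Cyp2a5 fell from 154 ± 31.2 to 6.15 ± 2.46 CPM and Scgb3a2 from 404 ± 38.3 to 48.9 ± 15 CPM.

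By list, 23 of 25 measured type 2 genes rose and none fell, in the test over all genes and also when adjusted over the list alone (camera adjusted p = 1.91e-14). Of 17 mucous cell genes 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 4.29e-06). Of 35 prostanoid and leukotriene genes 20 rose and 3 fell, or 21 and 3 adjusted over the list alone. Those that rose included the prostacyclin receptor gene Ptgir (log2 1.58) and the prostaglandin E2 receptor gene Ptger4 (log2 1.66). These were the 3 lists that held with an estimated correlation (adjusted p = 0.00658, 0.0138 and 0.0343 with an estimated correlation). All 25 cell cycle genes rose, adjusted over the list alone as well, among them Cdk1 and Ccna2, 6.83-fold and 6.91-fold (camera adjusted p = 1.03e-18, but adjusted p = 0.109 with an estimated correlation). Eosinophil granule genes Epx and Prg2 rose by log2 4.09 and 3.84, and of 11 eosinophil markers 7 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.499 with an estimated correlation). Of 22 T cell markers 18 rose, 18 adjusted over the list alone, with Il2ra and Ctla4 up by log2 2.07 and 2.27 (adjusted p = 0.42 with an estimated correlation).

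Of 16 club cell markers 14 fell and 1 rose, or 15 and 1 adjusted over the list alone, including Cyp2f2 (log2 -2.51; adjusted p = 0.339 with an estimated correlation). Of 19 ciliated cell markers 17 fell and 1 rose, the same numbers adjusted over the list alone, with the axonemal genes Hydin and Ccdc39 at log2 -1.50 and -1.29 (adjusted p = 0.129 with an estimated correlation). Of 14 alveolar type 1 markers 12 fell, or 13 adjusted over the list alone, including Cav1 (log2 -1.09) and Col4a3 (log2 -2.19; adjusted p = 0.499 with an estimated correlation). Of 15 alveolar type 2 markers 3 rose and 5 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.608). Of 28 fibroblast and matrix genes 13 rose and 5 fell, again the same numbers adjusted over the list alone (camera adjusted p = 0.0474, but adjusted p = 0.673 with an estimated correlation). Genes of contractile cells were split: Actg2 rose (log2 0.95) while Itga8 and Npnt fell (log2 -1.80 and -1.75), and 5 of 23 smooth muscle genes rose against 8 that fell, the same numbers adjusted over the list alone (camera adjusted p = 0.109). Among receptor and calcium signalling genes of smooth muscle, 18 of 45 fell and 5 rose, again with the same numbers adjusted over the list alone. Those that fell included the muscarinic receptor gene Chrm3 (log2 -1.44) and the angiotensin receptor gene Agtr1a (log2 -1.26; list adjusted p = 0.599 with an estimated correlation). Of 19 measured RGS genes 7 rose, Rgs4 among them, and 7 fell, including Rgs11 (log2 -1.90), with the same numbers adjusted over the list alone (camera adjusted p = 0.796). Myh6, a cardiac myosin heavy chain gene, fell from 695 ± 225 to 159.7 ± 111 CPM (log2 -2.47, and -1.60 without WT_Af 20).

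In total 8361 of 16126 tested genes changed in WT lungs, 4228 up and 4133 down (limma, Benjamini-Hochberg adjusted p under 0.05), and 2125 of them by at least 2-fold. Chil4, a chitinase-like gene near-identical to Chil3, rose in the test, but its WT_PBS mean of 104 ± 179 CPM came from WT_PBS 17 alone (309.9 CPM, against 0.786 and 0.564 CPM for Chil4 in WT_PBS 15 and 16), a library that also had Krt13, a squamous keratin gene, at 239.5 CPM. The rise of Chil4 was log2 6.33 with all libraries, 9.01 without WT_PBS 17 and from 4.92 upward without WT_PBS 15 or 16.

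The same exposure was compared in KO lungs. Retnla went from 81 ± 17.5 to 10097 ± 2712 CPM, Arg1 rose 175-fold, Ccl8 147-fold and the epithelial ion exchanger gene Slc26a4 46.1-fold. Muc5ac, Clca1 and Fcgbp rose by log2 4.56, 7.37 and 3.51, and Clca1 by 8.41 without KO_PBS 9 and 6.57 without KO_PBS 10. Il33, the epithelial alarmin gene, rose 8.26-fold to 483 ± 60.8 CPM. Falls included Cyp2a5 (log2 -4.15), the endothelial gene Esm1 (log2 -4.06) and the clock output gene Dbp (log2 -3.11). In total 9331 of 16126 genes changed, 4624 up and 4707 down, and 2574 by at least 2-fold (limma adjusted p under 0.05).

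In KO lungs 24 of 25 type 2 genes rose, 24 adjusted over the list alone, and 15 of 17 mucous cell genes rose and 1 fell, or 16 and 1 adjusted over the list alone. Both lists held with an estimated correlation (adjusted p = 0.0065 with an estimated correlation for each). Of 35 prostanoid and leukotriene genes 21 rose and 5 fell, or 22 and 5 adjusted over the list alone, with the leukotriene B4 receptor gene Ltb4r1 up by log2 1.95 (adjusted p = 0.0522 with an estimated correlation). All 25 cell cycle genes rose, 25 adjusted over the list alone (adjusted p = 0.144 with an estimated correlation). Of 20 endothelial markers 14 fell, 14 adjusted over the list alone, with the angiopoietin receptor gene Tek at log2 -1.72 and Aplnr at log2 -2.12 (adjusted p = 0.439 with an estimated correlation). In WT lungs 11 of these 20 fell and none rose, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.00456, but adjusted p = 0.499 with an estimated correlation). Of 22 T cell markers 5 rose and 1 fell, or 5 and 0 adjusted over the list alone, and the list was not called (camera adjusted p = 0.217). Sprr2a2 and Sprr2a3, near-identical cornified envelope genes whose reads cannot be told apart, rose by log2 8.21 and 7.93, with Sprr2a2 at 302.5 CPM in KO_Af 12, which also held Krt13 at 137 CPM, and at 122 and 123 CPM in KO_Af 13 and 14.

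The responses of both genotypes overlapped. Of the genes that rose, 3588 did so in WT and in KO, where independent lists would share 1212. Of those that fell, 3499 were shared, against 1206. The comparisons had no library in common. Across the 16126 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.886. Of the genes called in both genotypes, 4 rose in WT and fell in KO, and 15 fell in WT and rose in KO.

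**Figure D2:**
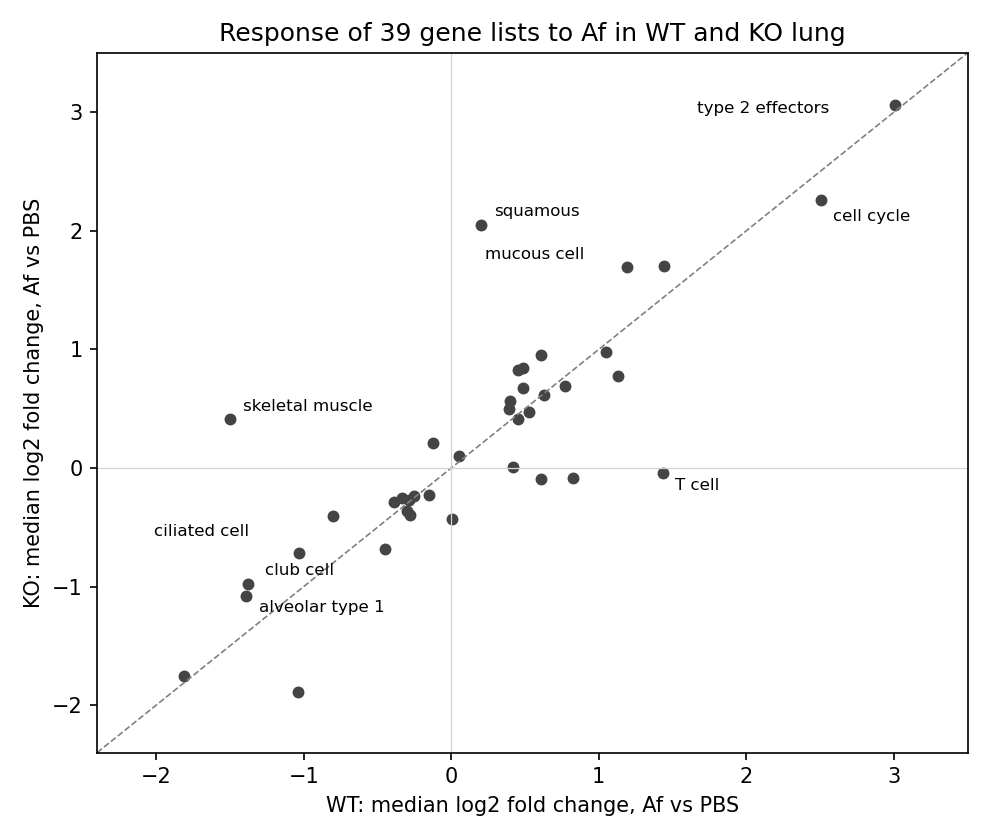
Median log2 fold change of each of 39 gene lists after Af in WT (x axis) and KO (y axis) lungs, each point a list and the dashed line equality. Type 2 effectors (3.01 and 3.06) and cell cycle genes (2.50 and 2.26) lie near the line, and T cell markers (1.43 and -0.04) below it.

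The effect of losing Rgs4 in unexposed lungs was compared in the PBS groups. Heat shock genes were lower in KO lungs: Hsph1, a chaperone gene, was at 32.1 ± 1.59 CPM against 239.7 ± 50.4 CPM in WT, and Dnajb1 at 47.8 ± 3.37 against 231 ± 114 CPM. Hsp90aa1 was lower by log2 -1.44, and the near-identical pair Hspa1a and Hspa1b by log2 -3.35 and -3.55 (-4.09 and -4.33 without KO_PBS 10). The glucocorticoid-induced genes Fkbp5 and Zbtb16 were lower in KO_PBS than in WT_PBS, 15.5 ± 2.64 against 139 ± 16.1 CPM and 18.2 ± 4.5 against 241 ± 18.5 CPM. Genes higher in KO lungs included the activation marker Cd69 (log2 1.63), the monocyte chemokine receptor gene Ccr2 (log2 0.97) and Ms4a4c (log2 1.62). Ighg1, an immunoglobulin heavy chain gene, was lower (log2 -3.15 ± 0.36 SE, limma adjusted p = 0.00162).

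By list, 7 of 20 endoplasmic reticulum folding genes fell under PBS, or 18 adjusted over the list alone, with the chaperone gene Hspa5 at log2 -0.82 and the stress-induced factor gene Ddit3 at log2 -0.67 (camera adjusted p = 2.94e-13, but adjusted p = 0.427 with an estimated correlation). Of 10 NK cell markers 4 rose, or 9 adjusted over the list alone, with the granzyme gene Gzma at log2 1.32 and Nkg7 at log2 0.96 (adjusted p = 0.427 with an estimated correlation). Of 16 neutrophil markers 2 rose, or 6 adjusted over the list alone (median log2 0.54, camera adjusted p = 0.00674, but adjusted p = 0.708 with an estimated correlation). Of 11 eosinophil markers 2 rose, or 4 adjusted over the list alone (median log2 0.21, camera adjusted p = 0.0127, but adjusted p = 0.708 with an estimated correlation). Of 9 red blood cell genes none passed over all genes and 2 rose adjusted over the list alone (median log2 0.45, camera adjusted p = 0.014, but adjusted p = 0.708 with an estimated correlation). Of 17 monocyte and interstitial macrophage markers 2 rose, or 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.43). Of 22 T cell markers none passed in limma, and 1 rose adjusted over the list alone (camera adjusted p = 0.00325, but adjusted p = 0.708 with an estimated correlation). Of 22 immediate early and heat shock genes 6 fell and 1 rose, or 7 and 5 adjusted over the list alone (adjusted p = 0.726 with an estimated correlation). Of 17 mucous cell genes 2 fell, the mucin gene Muc5b (log2 -1.06) and the goblet cell regulator gene Spdef (log2 -0.71), and 2 did so adjusted over the list alone (adjusted p = 0.427 with an estimated correlation). No smooth muscle contractile gene passed, over all genes or adjusted over the list alone, and of 45 receptor and calcium signalling genes 1 fell, the lysophosphatidic acid receptor gene Lpar1 (log2 -0.82), 1 adjusted over the list alone.

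In total 573 of 16126 genes differed between genotypes under PBS, 306 higher and 267 lower in KO, and 134 by at least 2-fold (limma adjusted p under 0.05). The count was 182 without KO_PBS 9, 131 without KO_PBS 10, 167 without KO_PBS 11, 334 without WT_PBS 15 and 246 without WT_PBS 17. In at least 1 of the 6 fits that each left out 1 PBS library, Zbtb16, Hspa1a, Hspa1b, Hspa5, Gzma, Nkg7, Muc5b, Spdef and Lpar1 lost their calls, with adjusted p up to 0.115 for Hspa1a without KO_PBS 11.

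The genotypes were also compared under Af. Rgs4, Hsph1, the ubiquitin ligase gene Trim65, Dnaja1, Hey1, Abi3bp and Fam193b were lower in KO_Af, and Ccdc190, Sult4a1, Ankrd37, Apold1 and Nanp were higher. Ccdc190 was at 11.7 ± 1.43 CPM in KO_Af and 0.343 ± 0.131 CPM in WT_Af. Hsph1 was at 66.1 ± 10.4 against 189 ± 45.7 CPM (limma adjusted p = 0.0122), and the endothelial gene Apold1 at 7.66 ± 1.46 against 2.24 ± 0.293 CPM (adjusted p = 0.00769). Fkbp5 was not called (log2 0.01, adjusted p = 0.996), and its KO_Af mean of 109.8 ± 94.9 CPM took in KO_Af 14 at 219 CPM, against 47.6 and 62.8 CPM of Fkbp5 in KO_Af 12 and 13. In total 14 genes passed, 6 higher and 8 lower in KO (limma adjusted p under 0.05), against 1807 at an unadjusted p under 0.05. The count was 110 without KO_Af 13, 6 without KO_Af 14, 3 without WT_Af 18, 6 without WT_Af 19 and 5 without WT_Af 20, and 14 without KO_Af 12. Rgs4, Ccdc190 and Trim65 were called in all 6 of these fits, Apold1 was not without WT_Af 18 (adjusted p = 0.0645) and Hsph1 was not without KO_Af 14 or WT_Af 18 (up to 0.0705). Hey1, Abi3bp, Fam193b, Dnaja1, Sult4a1, Ankrd37 and Nanp lost their calls in at least 3 fits, with adjusted p up to 0.255 without WT_Af 19.

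By list under Af, no gene of the smooth muscle contractile list passed over all genes, and 1 of 23 fell adjusted over the list alone. Of 16 neutrophil markers none passed over all genes or adjusted over the list alone, although the list was called (median log2 0.53, camera adjusted p = 6.36e-05; adjusted p = 0.546 with an estimated correlation). Of 11 eosinophil markers, 22 T cell markers and 17 mucous cell genes none passed over all genes or adjusted over the list alone, although the lists were called with the preset correlation. Eosinophil markers had a median log2 of 0.40 (camera adjusted p = 0.0121, but adjusted p = 0.812 with an estimated correlation). T cell markers had a median of -0.50, against 0.74 under PBS (camera adjusted p = 0.0102, but adjusted p = 0.812 with an estimated correlation), and mucous cell genes of 0.24, against -0.29 under PBS (camera adjusted p = 0.0213, but adjusted p = 0.426 with an estimated correlation). Of 9 red blood cell genes none passed over all genes and 1 rose adjusted over the list alone (median log2 0.33, camera adjusted p = 0.00563, but adjusted p = 0.806 with an estimated correlation). Of 19 circadian clock genes none passed over all genes and 5 fell adjusted over the list alone (adjusted p = 0.546 with an estimated correlation).

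The genotype difference was also averaged over both exposures. Ccdc190 was higher in KO by log2 3.63 ± 0.12 SE and Apold1 by log2 1.49 ± 0.13 SE. Lower in KO were Hsph1 (log2 -2.18), Dnaja1 (log2 -1.33), Dnajb1 (log2 -1.60), the natriuretic peptide clearance receptor gene Npr3 (log2 -1.67) and Ighg1 (log2 -2.01). The leukotriene synthesis genes Alox5 and Alox5ap were higher in KO by log2 0.36 and 0.42, while of 35 prostanoid and leukotriene genes 2 rose and 1 fell, or 4 and 1 adjusted over the list alone, and the list was not called (camera adjusted p = 0.379). Of 11 eosinophil markers 3 rose, or 4 adjusted over the list alone (median log2 0.36, camera adjusted p = 0.0011, but adjusted p = 0.772 with an estimated correlation), and of 16 neutrophil markers 2 rose, or 8 adjusted over the list alone (median log2 0.55, camera adjusted p = 1.45e-05, but adjusted p = 0.705 with an estimated correlation). Foxj1, the master regulator gene of ciliated cells, was lower (log2 -0.35, limma adjusted p = 0.00671). DESeq2, but not limma, called an interaction with Af for Foxj1 (log2 0.55, adjusted p = 3.70e-04) and Ighg1 (log2 2.38, adjusted p = 7.80e-04). DESeq2 also called one for Hsph1, Dnaja1 and Dnajb1. The averaged differences of these genes need not be alike under both exposures. Of 10 NK cell markers 3 rose, or 7 adjusted over the list alone (adjusted p = 0.705 with an estimated correlation), and of 19 circadian clock genes 3 fell, or 8 adjusted over the list alone (adjusted p = 0.705 with an estimated correlation).

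**Figure D3:**
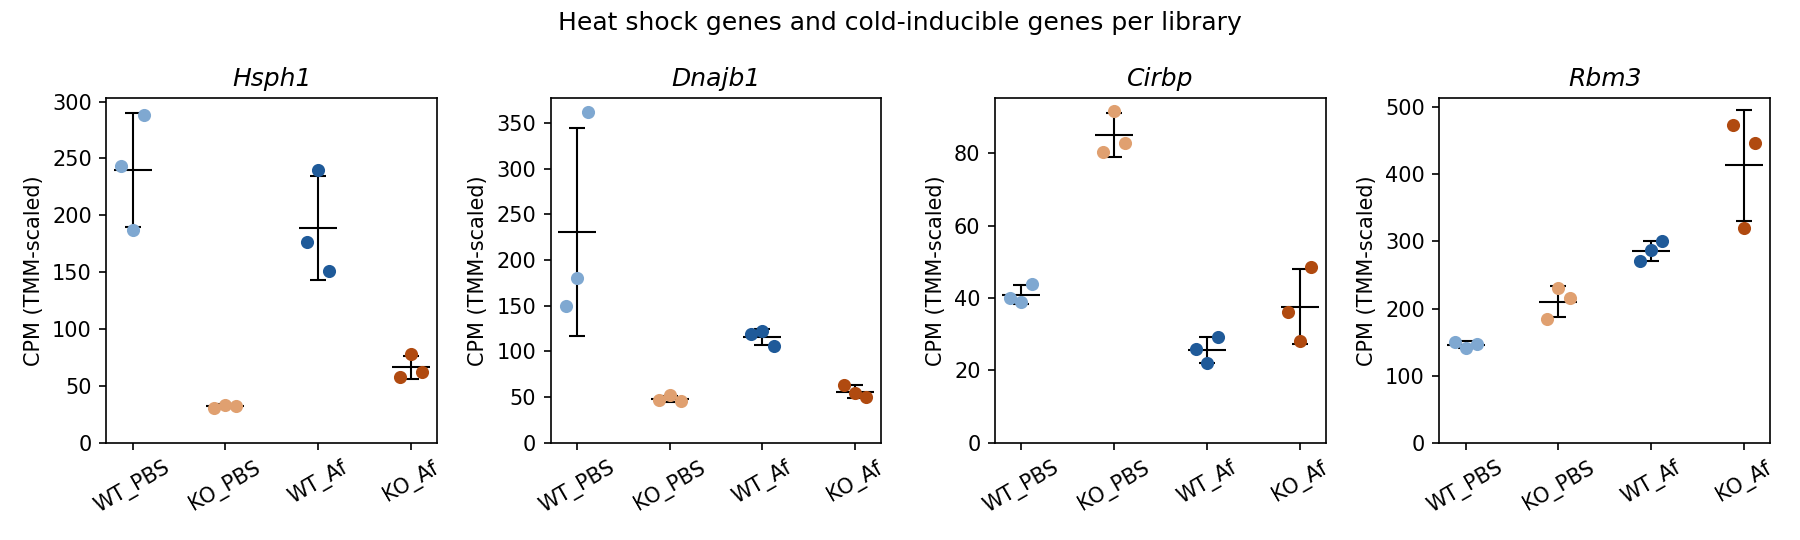
CPM of the heat shock genes Hsph1 and Dnajb1 and of the cold-inducible genes Cirbp and Rbm3 in each library, with points for libraries, a line for the group mean and bars for the SD (n = 3). Hsph1 averaged 239.7 CPM in WT_PBS and 32.1 CPM in KO_PBS.

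In total 349 genes differed in the averaged comparison, 168 higher and 181 lower in KO (limma adjusted p under 0.05), and 23 by at least 2-fold. The count was 122, 112 and 131 without KO_PBS 9, 10 and 11, 232 and 141 without WT_PBS 15 and 17, 103 and 177 without WT_Af 19 and 20, and 624 and 814 without KO_Af 12 and 13. Alox5ap lost its call in 5 of the 12 fits, with a highest adjusted p of 0.0692 without WT_Af 19. Calls under PBS and under Af shared 7 genes in the same direction, where independent lists would share 0.246. Rgs4, Hsph1, Dnaja1 and Trim65 were lower, and Ccdc190, Apold1 and Gm7068 higher. Rgs4 is the deleted gene, and Ccdc190 and Gm7068 lie near it. Sult4a1 was called in both with opposite signs. Across all tested genes the genotype differences under PBS and under Af correlated only weakly (Pearson r = 0.132). Of the 573 PBS calls 384 (67.0%) had the same sign under Af.

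Genes near the targeted locus were tested as a set. Ccdc190 (chromosome 1, 169928648 to 169934653, plus strand, GRCm38) begins 181 kb from the end of Rgs4. Of 185 tested genes within 10 Mb of Rgs4, itself left out, 16 differed by genotype in the averaged comparison, or 8.65%, against 2.08% of the 15940 other genes (odds ratio 4.45, 95% interval 2.46 to 7.55, two-sided Fisher's exact p = 2.66e-06). They included Uhmk1 (log2 -0.40), the NK cell adaptor gene Sh2d1b1 (log2 -0.87) and Gm7068, named Catspere1 in the reference (log2 1.72). With array weights the odds ratio was 1.49 (Fisher's exact p = 0.0204). Fcer1g and Ifi208, which leukocytes express, were among the 16. A list of 77 measured genes flanking Rgs4, tested by camera for a shift in a shared direction, was not called averaged (adjusted p = 0.515; 4 rose and 2 fell, or 8 and 8 adjusted over the list alone). Nor was it under PBS (adjusted p = 0.466; 4 rose and 5 fell, or 10 and 7) or under Af (adjusted p = 0.497; 1 rose and none fell, or 3 and 3).

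**Figure D4:**
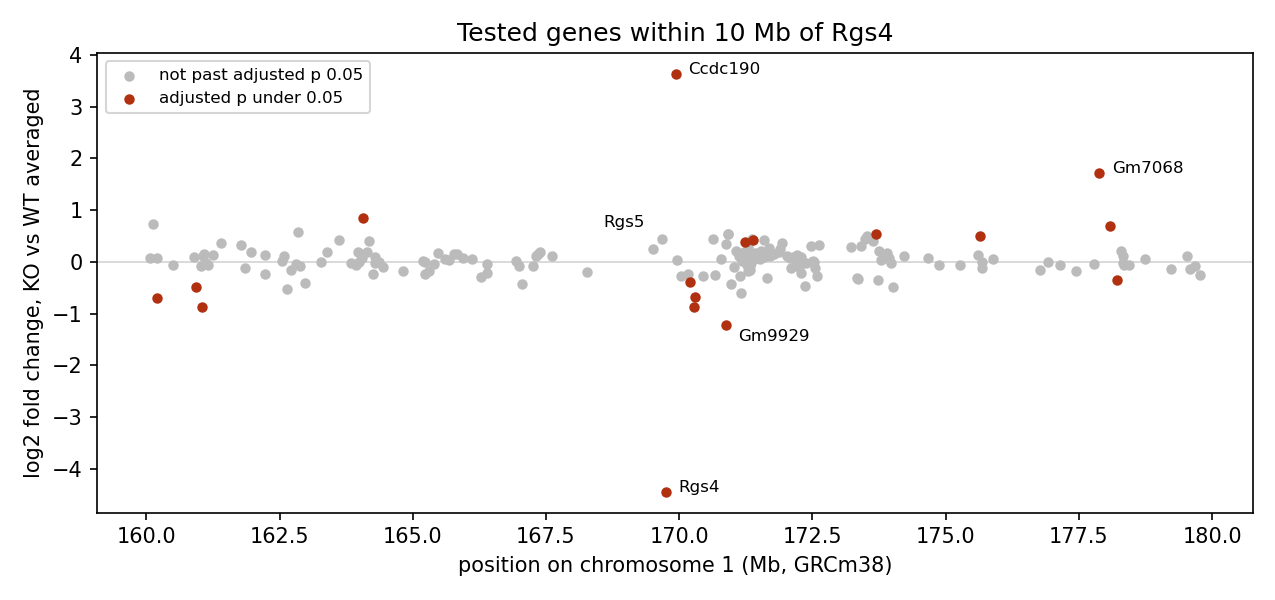
Log2 fold change between KO and WT, averaged over both exposures, for tested genes within 10 Mb of Rgs4 against their position on chromosome 1 (Mb, GRCm38), with red points at adjusted p under 0.05. Rgs4 lies at -4.45 and Ccdc190 at 3.63.

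Whether the Af response depended on genotype was tested with the interaction term. Sult4a1, a sulfotransferase gene, was the gene that passed: Af lowered it in WT from 2.97 ± 1.75 to 0.301 ± 0.0798 CPM and raised it in KO from 0.348 ± 0.194 to 5.22 ± 1.7 CPM (log2 4.68 ± 0.56 SE, limma adjusted p = 0.0465). The interaction of Rgs4 itself was log2 -0.71 (adjusted p = 0.315). At an unadjusted p under 0.05 there were 1750 genes, edgeR called 1 and DESeq2 366. By list, T cell markers had a median interaction of log2 -1.35 and mucous cell genes of log2 0.49, with 1 T cell gene lower and 2 mucous genes higher adjusted over the list alone and none over all genes (adjusted p = 0.563 and 0.1 with an estimated correlation). The count of 1 became 0 without KO_PBS 9, KO_PBS 10, WT_PBS 15, WT_PBS 16, WT_Af 18, WT_Af 19 or WT_Af 20, and 32, 187 and 9 without KO_Af 12, 13 and 14. In a simulation on 16126 genes this test recovered 34% of 2-fold interactions and 2% of 1.5-fold ones. The simulation held no Af response and drew genes independently, so recovery in the real libraries may differ.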

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

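In this part the test on order of handling was chosen only after the result was seen. The first results given differed between genotypes in their response to Af by the interaction term. Sult4a1 passed with adjusted p = 0.0465 in limma (log2 4.68 ± 0.56 SE): Sult4a1 was at 0.945 to 4.06 CPM in WT_PBS, 0.225 to 0.384 in WT_Af, 0.223 to 0.571 in KO_PBS and 3.43 to 6.80 in KO_Af. It lost its call in 8 of the 12 fits that each left out 1 library, with adjusted p up to 0.161 without KO_PBS 10. Over 100 splits of the genotype labels within exposure, the real one included, 10 gave as many interaction genes as the real 1, and the highest other gave 244. A split that turns the labels of 1 exposure carries the genotype difference itself into the interaction term, so these splits do not decide whether chance can be excluded. Removing the averaged genotype difference first does not mend this, as that difference is estimated with the real labels.

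With the preset correlation 13 lists had an interaction, none of which held with an estimated correlation, where the smallest adjusted p was 0.1. Higher in the KO response were endoplasmic reticulum folding genes (camera adjusted p = 3.28e-08), mucous cell genes (3.55e-04), type 2 effectors (0.00674), fibroblast and matrix genes (0.00674), skeletal muscle genes (0.00895), monocyte and interstitial macrophage markers (0.018), ciliated cell markers (0.036) and arginine and polyamine genes (0.0491). Lower were NK cell markers (1.67e-06), T cell markers (8.4e-06), endothelial markers (0.00193), the RGS family (0.00497) and cell cycle genes (0.027).

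Hsph1 and Dnaja1 were lower in KO lungs under both exposures, and further heat shock genes were under PBS and averaged. Under Af, leaving out 1 library cost Dnaja1 its call in 5 of 6 fits and Hsph1 in 2, though both stayed lower (log2 -0.77 and -1.31 or below). Under PBS the near-identical Hspa1a and Hspa1b lost theirs in 4 and 3 of 6 fits. In the averaged comparison at least 4 of Hspa1a, Hspa1b, Hsph1, Dnajb1 and Dnaja1 stayed past adjusted p 0.05 whichever of the 12 libraries was left out. For that comparison alone, a single library is argued against. Members of a list of heat shock factor 1 targets whose calls had not been seen were lower too, 9 of 9 with a median log2 of -0.61 (camera p = 0.00413 with an estimated correlation), which is consistent with a coordinated change; a first run that also left out Hsp90aa1 and Hspe1 gave 7 of 7 and p = 0.00428. Cirbp and Rbm3, which are induced by cold, were higher in KO in the averaged comparison, but within groups a correlation of their mean with the heat shock mean was not shown (Pearson r = -0.228, permutation p = 0.527; Spearman rho = -0.0629, p = 0.856; r = 0.0152 without the 2 farthest libraries), so body temperature or handling at harvest stays open. Order of handling cannot be told apart from genotype, because 0 KO libraries have a number above the lowest WT number.

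Ccdc190 was higher in every KO library. A flanking segment from another strain may account for it, since genes within 10 Mb of Rgs4 differed more often than others (odds ratio 4.45). Transcription from the targeted locus stays open: Ccdc190 lies on the other strand, 181 kb away on the upstream side of Rgs4, which had been set down as evidence against it, but this position is fixed before any data and a transcript in that direction was not tested. Sequence reads, which would show a segment directly, were not used here.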

How the results depend on the processing

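The comparisons were refitted under other settings, of which edgeR, DESeq2 and the fit without WT_PBS 17 and KO_Af 12 were chosen after seeing the data. Apart from a fold threshold, the counts of genes after Af ran from 7081 to 10817 in WT and from 7933 to 11624 in KO. The overlap of both responses held 6179 to 9137 shared genes. The Rgs4 differences (log2 -3.11 to -4.66 under PBS and -3.90 to -5.30 under Af) kept their direction and their side of the threshold. With a fold of at least 2 the counts were 2125 and 2574 for Af in WT and KO, 134 and 7 for genotype under PBS and Af, and 23 averaged. Without a filter, genotype counts were 373 under PBS and 188 averaged, and 0 for the interaction. A filter of 5 CPM gave 9 under Af and 0 for the interaction. Array weights gave 2646 under PBS, 2204 under Af, 3224 averaged and 1602 for the interaction. The 2 compared groups alone gave 1124 under PBS and 3 under Af. A pseudocount of 2 gave 6 interaction genes and no trend 0. DESeq2 gave 1216, 189, 1162 and 366 for genotype under PBS, under Af, averaged and the interaction, where edgeR gave 566, 13, 334 and 1. Without WT_PBS 17 and KO_Af 12 the counts were 615, 15, 311 and 1. The cause of these shifts was not tested. Leaving out 1 library gave 131 to 430 genes under PBS, 3 to 110 under Af, 103 to 814 averaged and 0 to 187 for the interaction. Genes near Rgs4 kept an odds ratio above 1 in the other settings (1.49 to 5.58, Fisher's exact p up to 0.0204). Neither this test nor the overlap of both responses was refitted with 1 library left out. With an estimated correlation the lists called were 3 and 2 for Af in WT and KO and 0 in each of the 4 genotype and interaction tests.

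Over 102 named gene results and 1798 recomputed values, 1692 kept their side of the threshold and 105 lost the call (73 of them with 1 library left out), and 0 reversed. These totals mix stable and less stable results. With 1 library left out, all 35 and 16 called results for Af in WT and KO kept their calls. Calls were lost in at least 1 fit for 9 of 20 genotype results under PBS, 9 of 12 under Af, 1 of 11 averaged and the 1 interaction gene. No paired analysis was possible because every library has its own number and the groups share none. Depth limits low genes: 3 reads correspond to 0.0983 to 0.144 CPM.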

Other observations

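The list tests in the last paragraph of this part used lists made after the data were seen, and the tests on squamous genes and glucocorticoid receptor targets were set down before their results were seen but on patterns already noticed. In WT lungs the clock output genes Tef and Per3 changed by log2 -1.99 and -2.14, and 11 of 19 clock genes fell against 5 that rose, or 12 and 5 adjusted over the list alone (limma and camera; list adjusted p = 0.0373, but adjusted p = 0.499 with an estimated correlation). In KO lungs 10 clock genes fell and 5 rose, the same numbers adjusted over the list alone, and the list was not called (camera adjusted p = 0.169). Of 15 cardiac muscle genes 6 fell in WT and 8 in KO, or 9 in each adjusted over the list alone, with no test of its source (adjusted p = 0.599 and 0.641 with an estimated correlation). Of 14 alveolar macrophage markers 4 rose and 5 fell in WT, the same numbers adjusted over the list alone, with the scavenger receptor gene Marco down by log2 -1.87 and Chil3 up by log2 4.16.

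Some squamous keratin genes were high in WT_PBS 17 and KO_Af 12. Krt13 was at 239.5 and 137 CPM against a median of 0.106 CPM in the other 10 libraries, and Krt4 at 174 and 131 against 0.715 CPM. Krt78 was at 9.07 and 5.43 CPM, against at most 0.524 CPM in the other 10 libraries. Krt14 was at 12.9 and 5.62 CPM, against at most 4.36 CPM. Krt6a, Krt6b and Krt5 were not high in both. Krt6a and Krt6b were at 43.6 and 93.7 CPM in WT_PBS 17 but at 0.826 and 0.433 CPM in KO_Af 12. Krt5 was at 22.1 CPM in KO_Af 12, below the highest of the other 10 libraries (28.9 CPM). Squamous tissue included at dissection is a candidate explanation that stays open: 12 of 21 measured squamous genes exceeded 10 times the median of the other 10 libraries in both, where the rule set down asked for a majority. The majority depends on 3 members, Krt6b, Sprr3 and Dsg3. Their median in the other libraries was 0, so that any read passed, and without them 9 of 18 passed. Sprr3 was at 14.8 CPM in WT_PBS 17 and 13.4 CPM in KO_Af 12, against at most 0.138 CPM in the other 10 libraries. Dsg3 was at 8.08 and 1.14 CPM, against at most 0.0440 CPM. Krt6b in KO_Af 12 was near its highest level in the other 10 libraries (0.308 CPM). Among the members kept, Krt6a and Dsc3 passed in KO_Af 12 at levels below their highest in the other 10 libraries (0.964 and 4.73 CPM). A first run that added 0.05 CPM to each value gave 10 of 21, a minority. The other 4 libraries of those groups differed from the 6 libraries of the remaining groups by a median log2 of 0.0874. A difference by genotype alone or by exposure alone cancels in this comparison. It therefore argues only against an effect of genotype and exposure in combination. Krt13 was at most 0.506 CPM in the other 10 libraries, which include the other libraries of the same groups.

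Glucocorticoid receptor targets were lower in KO_PBS for Fkbp5 and Zbtb16. As a hypothesis of a coordinated change, the 15 list members not seen before were tested: 12 lay below 0, 1 fell past the threshold, and the median log2 was -0.60, but camera with an estimated correlation gave p = 0.228, and p = 0.175 in a first run over 14 members that also left out Dusp1, so a coordinated change was not shown and may be limited to a few genes.

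Other splits of the libraries gave the following. Under PBS 573 genes differed by genotype and the highest other of 10 splits gave 1, under Af 14 and 6, for Af against PBS in WT 8361 and 0, and in KO 9331 and 0; in each, 1 split of 10 was as large, and 10 splits are too few for a share under 0.05. For the averaged comparison 1 of 100 splits, the real one, gave as many as 349 genes and the highest other gave 66. For this count, chance labelling of the libraries is excluded at 0.05. A difference that follows library number is not, because library number coincides with genotype.

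Lists made after the data were seen gave the following. Of 16 heat shock factor 1 targets 15 fell under PBS and 15 averaged over both exposures, or 16 in each adjusted over the list alone. Camera gave adjusted p = 0.00854 and 0.00997 with an estimated correlation. Under Af 2 fell, or 14 adjusted over the list alone (camera adjusted p = 0.0626 with an estimated correlation). Several of these members had been seen before the list was made. The interaction of genotype and Af over these targets had a median log2 of 0.82 (adjusted p = 0.0505 with an estimated correlation). Of 20 glucocorticoid receptor targets 5 fell under PBS, or 9 fell and 1 rose adjusted over the list alone. Their median log2 was -0.64 (camera adjusted p = 0.151 with an estimated correlation). Under Af none passed in limma over all genes and 1 rose adjusted over the list alone. The median was 0.52 (camera adjusted p = 1.96e-06, but adjusted p = 0.182 with an estimated correlation). Averaged, 3 fell, or 4 fell and 1 rose adjusted over the list alone. The median was then 0.03 and the mean -0.20 (camera adjusted p = 0.336). Their interaction had a median log2 of 1.20 (adjusted p = 0.0505 with an estimated correlation). The mean log2 of these targets was 7.50 in KO_Af 14, against 6.51 and 6.44 in KO_Af 12 and 13 and 6.12 to 6.53 in WT_Af. Without KO_Af 14 the median under Af was 0.32 and the mean 0.12 (camera p = 0.134, and 0.478 with an estimated correlation). The median interaction was 0.92 without KO_Af 14, 1.24 without KO_Af 12 and 1.46 without KO_Af 13. Camera with an estimated correlation gave p = 0.00504, 0.0401 and 0.0234 in that order, not adjusted over lists. Of 2 cold-inducible genes 1 rose under PBS, none passed under Af and both rose averaged. Adjusted over the list alone, both rose in each comparison (camera adjusted p = 0.0606, 0.0877 and 0.0428 with an estimated correlation). Of 12 squamous genes that entered the test none passed in limma between genotypes under PBS, under Af or averaged (adjusted p = 0.381, 0.622 and 0.747 with an estimated correlation).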
